A study of Mus musculus with 4 samples.

How the data were processed

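Total RNA was profiled in 4 mouse libraries from OG2MEF cultures on day 9 of reprogramming. The samples were labelled as wild-type SOX17 in 2 libraries and SOX17-V118M in 2 libraries. Per the labels' protocols, RNA was extracted with TRIzol and libraries were made with a TruSeq Nano RNA kit. The submitters' processing notes name mm10, FastQC, RSEM, Bowtie2 and DESeq2, without a version or a role for each. The normalization of the table is not given in the sources used here.

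The deposited table holds a score for each of 22369 genes in each library. These scores are whole numbers, but they are not raw counts. The 4 sorted columns held the same value at 76.7% of ranks, and the largest difference at any rank was 122. In each library 10 genes shared the highest value, 61186. The column totals differed by at most 0.0321% of the smallest. Such columns are what full-quantile normalization within bins of genes and then between libraries produces, so the values are called quantile-normalized here. The depth of the libraries is therefore unknown, and no counting intervals or detection floors are given. Differences among the most abundant genes are compressed, because several genes share a single value there. Library totals and shifts that affect most genes cannot be read from such values.

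Each gene was matched to the GENCODE M21 annotation of GRCm38, the assembly also called mm10, through the transcript given in the table. Of the transcripts, 22304 were found, and 95.9% of these had a start site within 1 base of the annotation. Coordinates and gene types were taken from the annotation, with positions counted from 1. Whether reads were assigned by strand is not given in the sources used here, and reads of near-identical family members (such as Krt16 and Krt17, the Zscan4 and Oas families, or the beta-globin genes) could be split between copies.

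The planned test for counts was replaced by the one planned for a normalized unit, because the values are not counts. Values were transformed as log2(value + 1), and genes with a value of at least 1 in at least 2 libraries were kept, leaving 19547. limma 3.58.1 in R 4.3.3 was fitted with group as the only term and with the trend and robust options. Tests were two-sided with Benjamini-Hochberg adjustment over all genes tested. Log2 fold changes are V118M minus wild type on the log2(value + 1) scale, which understates changes of low genes. No fold is given for a gene listed at 0 in both libraries of a group. The labels do not say that replicates were separate cultures, so p-values measure the spread between these samples, which may be technical.

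Before the data were examined, 27 gene lists were fixed: delivered factors, pluripotency, primed pluripotency, epithelial, fibroblast, endoderm, endothelial, trophoblast, neural, mesoderm and muscle, keratinocyte, germline, 2-cell-like, leukocyte, erythroid, adipocyte and chondrocyte, interferon response, inflammation, p53, S phase, G2 and M phase, glycolysis, respiratory chain, Wnt, Hedgehog and BMP targets, sex-linked, mitochondrially encoded, and immediate early genes. Lists with at least 5 tested genes, the delivered factors left out, were tested with camera at a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over 24 lists. The camera test asks whether the test statistics of a list's genes are on average higher or lower than those of all other genes. The test was repeated with an estimated correlation, and fry was run on the same lists. Members passing the gene test are counted over all genes tested and adjusted over the list alone.

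The genes named were set by a rule fixed in advance: the delivered factors Sox17, Sox2, Klf4 and Pou5f1; the 12 highest and 12 lowest log2 fold changes among genes with adjusted p under 0.05; up to 4 passing genes of each list; and the 1 gene with the smallest p of each list with none. No gene passed over all genes tested, so the rule gave the delivered factors and 1 gene per list. Other genes are said to be chosen after their values were seen.

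The gene test and the list test were run on data simulated for this comparison, with 19547 genes, 200 of them changed, in 20 simulations. The changed genes were drawn from those with a mean log2 value of at least 5, so the shares called do not cover lower genes. Noise was independent between genes, with no outlying library or length trend, so the list results hold for uncorrelated genes only. The gene test called 1.13% of 2-fold, 55.8% of 4-fold and 84.8% of 8-fold changes, and 99.6% of changed genes had the right direction. On average 4.5 of 89.75 called genes were unchanged. An interferon list moved 2-fold was called in 100% of simulations with the preset correlation and in 0% with an estimated correlation.

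Alternatives were other pseudocounts (0.1 and 5), no filter, a stricter filter, the replicate number as a block, each library left out, and both other list tests. Removal of a trend on transcript length and GC content, array quality weights, and counts within lists under these settings were added after the data had been seen. A motif search was not made here, and results for some single genes are not reported here.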

Results

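Gene expression was measured by RNA sequencing in OG2MEF cells, mouse embryonic fibroblasts carrying an Oct4-driven green fluorescent reporter, on day 9 of reprogramming. The protocol in the labels describes retroviral delivery of Sox2 and Klf4 together with OCT4, SOX17, SOX17-V118M or a fluorescent protein, then culture in mouse embryonic stem cell medium with LIF and vitamin C. It does not say which combination each library received. The 4 libraries comprised 2 labelled as wild-type SOX17 and 2 labelled as SOX17-V118M, a form of this endodermal transcription factor with a missense change. Quantile-normalized values summed to between 12855482 and 12859613 per library, with a median of 76 over the 22369 genes in each. Between 3291 and 3366 genes were listed at 0.

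The factors listed in advance as delivered were examined ahead of the other genes. Sox17 (ENSMUSG00000025902, chromosome 1, 4490931 to 4497354, minus strand) had values of 3484 and 2880 in the wild-type libraries and 3016 and 2396 in the V118M libraries. Its log2 fold change of -0.24 was close to its standard error of 0.19 (limma adjusted p = 0.951), and it ranged from -0.40 without V118M replicate 1 to -0.07 without V118M replicate 2. Without wild-type replicate 1 or 2 it was -0.10 or -0.37. Pou5f1, which encodes OCT4 (chromosome 17, 35506018 to 35510772), was at the shared highest value of 61186 in all 4 libraries, so no difference in its level could be seen. Klf4 (chromosome 4, 55527143 to 55532466) was at 29444 in 3 libraries and at 17589 in V118M replicate 2. Sox2 (chromosome 3, 34650405 to 34652461) was at 2, 2, 4 and 2, near the bottom of the scale. If virus transcripts are counted in the table, these values gave no sign of delivered Sox2. Myc, a factor of the classical reprogramming mix and a member of the same list, stood at 19002 in both wild-type libraries and at 22700 and 14813 in the V118M libraries. None of the 5 listed factors passed over all genes or adjusted over the list alone. Adjusted over the list alone, Klf4 and Myc passed as lower without V118M replicate 1, and Myc and Sox2 as higher without V118M replicate 2. In these fits the wild-type values of each of the 3 genes were tied. The table has no sequence information, so the mutation itself could not be seen in it.

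The comparison of V118M with wild-type SOX17 asked how the mutation changes the expression program of cells under reprogramming. Interferon-induced genes had the largest median shift of the 24 lists tested, and their list median was 1.07 and 1.5 log2 units above the wild-type mean in V118M replicates 1 and 2. The G2 and M phase and S phase lists were called as higher by camera and the p53 list as lower, at a preset correlation. None of their members passed over all genes or adjusted over the list alone, and with an estimated correlation their adjusted p was 0.399, 0.507 and 0.399. The pluripotency list, to which the study's title refers, was not shifted past the threshold. At the level of single genes, 0 of 19547 passed an adjusted p of 0.05 (limma, lowest adjusted p = 0.205), so 0 also passed with a change of at least 2-fold. At an unadjusted p under 0.05 there were 784 genes, 451 higher and 333 lower in V118M, where 977 would be reached by chance alone. Splitting the same libraries by replicate number gave more such genes, 1139, and the remaining split gave 402. On the same genes the count for V118M against wild type was 588 with array quality weights. It was 1007 with the length and GC trend removed and 1204 with the replicate block. The groups did not overlap in 28.0% of tested genes, against 33.3% by chance for 2 against 2. Of the 24 lists tested, 10 were called by camera with its preset correlation, 8 higher and 2 lower, and 0 were called with an estimated correlation or by fry. In the simulations the test with an estimated correlation called a 2-fold shift of the interferon list in 0%. Calls lost with that test, here and below, therefore decide nothing by themselves.

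V118M replicate 2 stood apart from the other libraries. Across 12661 genes with a mean log2 value of at least 5, its Pearson correlation with the others was 0.954 to 0.964, while the other 3 libraries correlated with each other at 0.986 to 0.990. The leading principal component held 55.5% of the variance and placed V118M replicate 2 at 95.3 and the other 3 libraries between -37.1 and -28.1.

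**Figure D1:**
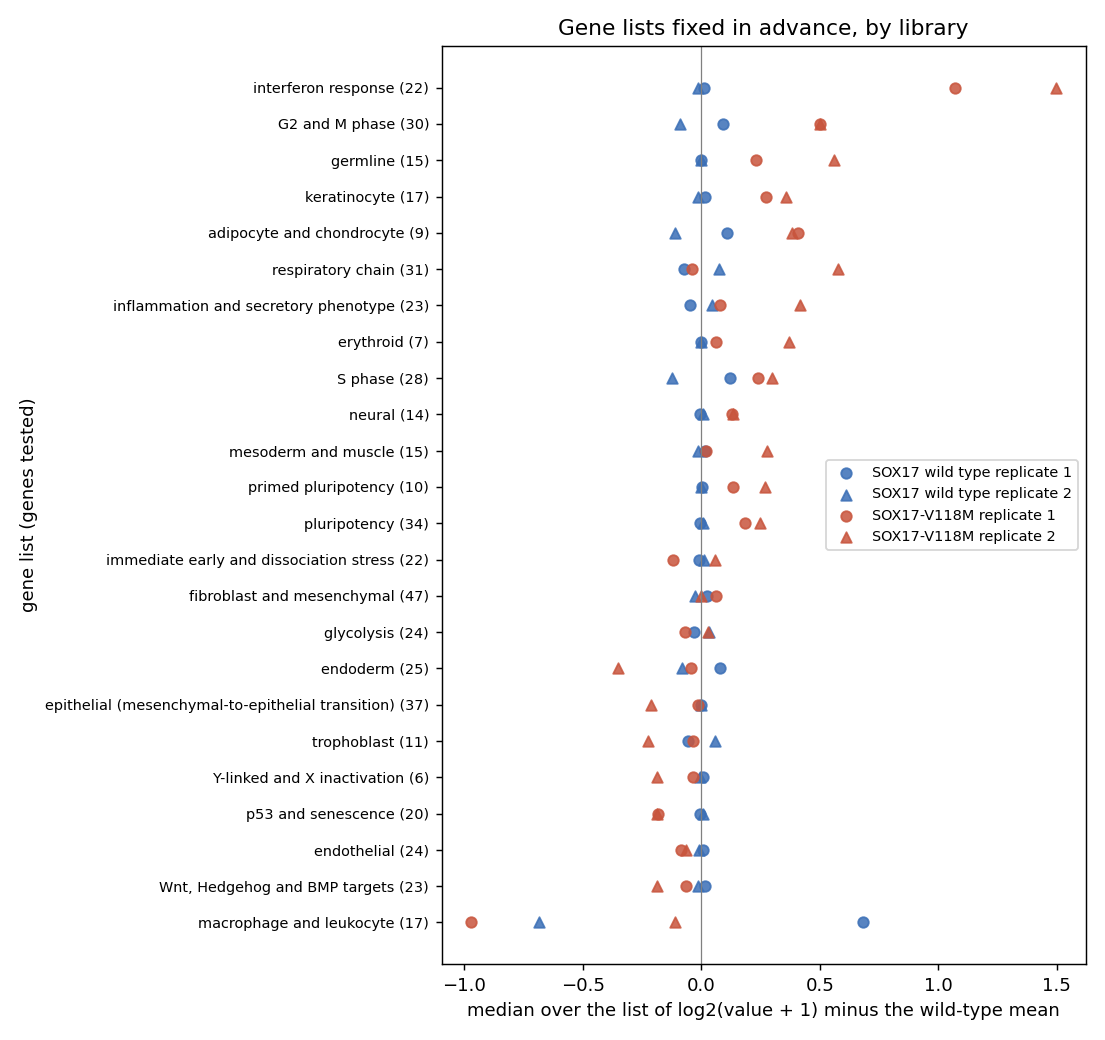
Each point is the median over a gene list of log2(value + 1) in a library minus the mean of the wild-type libraries, with the number of genes tested in brackets, blue for wild type and red for V118M. Interferon response genes lie at 1.07 and 1.5 in the V118M libraries, and the respiratory chain list is raised in V118M replicate 2 (0.58) but not in V118M replicate 1 (-0.04).

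Interferon response genes, which encode antiviral effectors and their regulators, were higher in V118M in 22 of 22 tested members, with a median log2 fold change of 1.30. Of these, 19 rose when adjusted over the list alone and 0 over all genes tested, and the groups did not overlap in 19. Irf7, the transcription factor that amplifies type I interferon signalling (chromosome 7, 141262706 to 141266481), was at 49 ± 1.41 (SD, n = 2) in wild type and 267 ± 18.4 (SD, n = 2) in V118M. Its log2 fold change was 2.42 with a standard error of 0.20 (limma adjusted p = 0.205). Chosen after their values were seen, Oas2, an activator of RNase L, was at 38 and 28 against 310 and 230, and the ubiquitin-like modifier Isg15 at 9 and 15 against 81 and 196. The 3 members that did not pass the list-alone test, also named after their values were seen, were Mx1 (21.5 against 24.5 on average), Ifit2 (76 against 84) and Cxcl10 (3.5 against 5). The camera adjusted p was 9.37e-23, with adjusted p = 0.295 with an estimated correlation. This list's estimated correlation was 0.0268, near the preset 0.01. The estimate was 0.303 for G2 and M phase, 0.406 for leukocyte genes, 0.449 for S phase and 0.861 for the respiratory chain. The preset p-values of those other lists may therefore be too small. In the simulations the test with an estimated correlation called a 2-fold shift of the interferon list in 0%. The lost call therefore does not show that correlation between genes accounts for the shift. Without V118M replicate 2 the count adjusted over the list alone was 3, without V118M replicate 1 it was 8, and without wild-type replicate 1 or 2 it was 8 or 11, with fewer libraries in each of these fits. The list median without V118M replicate 2 was 1.07.

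**Figure D2:**
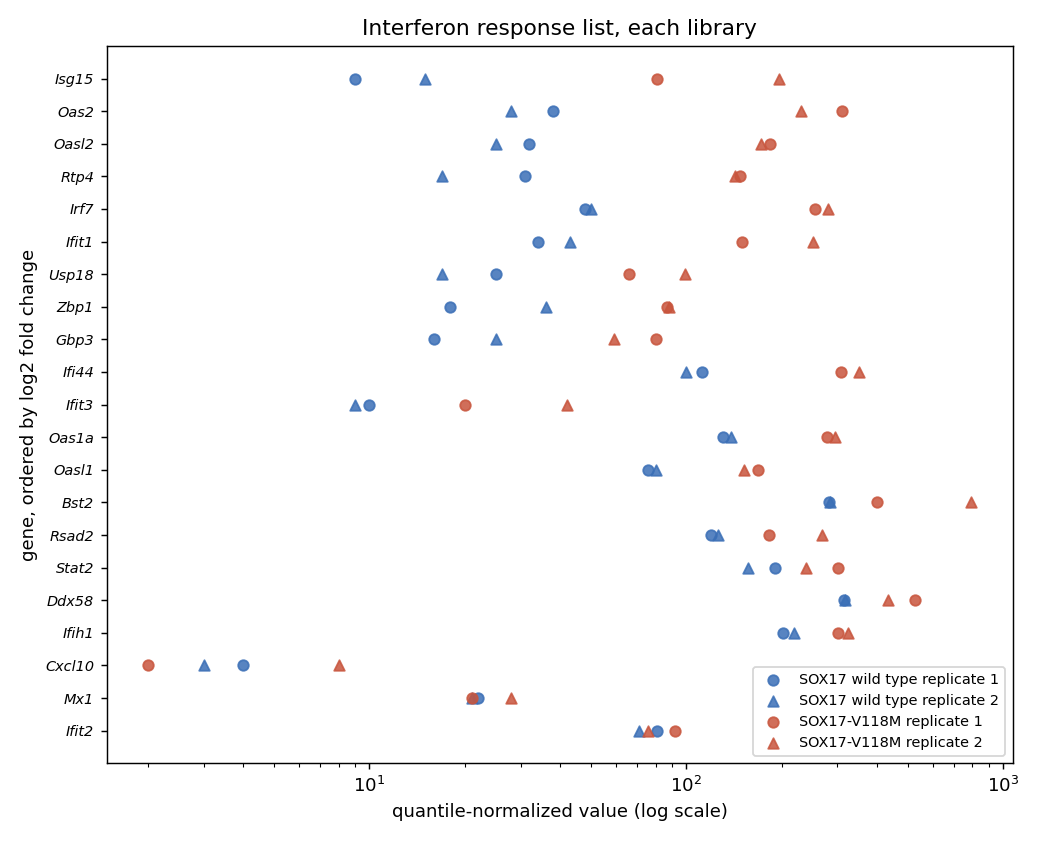
Values of 21 of the 22 tested interferon response genes on a log axis, each point a library, blue for wild type and red for V118M, ordered by log2 fold change. The groups do not overlap for 18 of the genes drawn, with Isg15 (log2 fold change 3.33) at the top.

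In the G2 and M phase list 29 of 30 members were higher, with a median log2 fold change of 0.48, and the groups did not overlap in 27. Birc5, the mitotic protein survivin (chromosome 11, 117849251 to 117855743), was at 189 ± 4.24 in wild type and 401.5 ± 99.7 in V118M (SD, n = 2 each; log2 fold change 1.06). In this list 0 members passed over all genes or adjusted over the list alone, and 11 had an unadjusted p under 0.05. Adjusted over the list alone, 9 rose with a length and GC trend removed from each library. The list median was 0.50 without V118M replicate 1 and 0.50 without V118M replicate 2. The camera adjusted p was 4.90e-16, and adjusted p = 0.399 with an estimated correlation. In the S phase list 26 of 28 members were higher, by a median of 0.23, and 0 passed over all genes or adjusted over the list alone. The replicative helicase subunit Mcm6 was at 1167 and 1016 in wild type against 1453 and 1544 in V118M. Its camera adjusted p was 7.87e-07, and adjusted p = 0.507 with an estimated correlation. Without wild-type replicate 2 the S phase median was 0.13. The p53 and senescence list was lower in 16 of 20 members, with a median of -0.14 (camera adjusted p = 0.0114, and adjusted p = 0.399 with an estimated correlation). The p53-induced regulator Trp53inp1 was at 2138 and 2052 against 1534 and 1294. None of the p53 list passed over all genes or adjusted over the list alone, and its camera call was lost without V118M replicate 1 (adjusted p = 0.546).

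Of 44 listed pluripotency genes 34 passed the filter and were tested, among them Pou5f1, tied at the shared highest value. Tested members were higher in 20 and lower in 13 cases, with a median log2 fold change of 0.10 (camera adjusted p = 0.119, fry adjusted p = 0.0630). None passed over all genes or adjusted over the list alone. Utf1, a chromatin factor of embryonic stem cells (chromosome 7, 139943789 to 139945112), was at 13.5 ± 4.95 in wild type and 35.5 ± 3.54 in V118M (SD, n = 2 each), with a log2 fold change of 1.37 (limma adjusted p = 0.951). Chosen after its values were seen, Nanog was near the bottom of the scale, at 1 and 8 in wild type and 6 and 6 in V118M. Without wild-type replicate 2 the list median was 0.13 and the camera adjusted p 0.0485. Without V118M replicate 1 the list median was 0.25, with adjusted p = 0.886, and without V118M replicate 2 it was 0.18, with adjusted p = 0.0944. Primed pluripotency genes had a median of 0.13 over 10 members (camera adjusted p = 0.0848). The list was called, with a median of 0.15, when the length and GC trend was removed (adjusted p = 0.0486), and its median was 0.27 without V118M replicate 1 (adjusted p = 0.290). Pou3f1 in that list was at 8 and 4 against 13 and 42.

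Epithelial genes, which are switched on in the mesenchymal-to-epithelial transition of reprogramming, had a median log2 fold change of -0.11 over 37 members (camera adjusted p = 0.119). The median was -0.01 without V118M replicate 2 and -0.21 without V118M replicate 1. The tight junction gene Cldn6 was at 70 and 87 in wild type and 62 and 36 in V118M. Fibroblast and mesenchymal genes had a median of 0.003 over 47 members, 24 higher and 21 lower (camera adjusted p = 0.368), and without V118M replicate 2 the camera adjusted p was 0.0311, with a median of 0.06. Periostin (Postn), a matrix protein, was at 1263 and 1098 against 1889 and 1744. None of either list passed over all genes or adjusted over the list alone.

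Keratinocyte genes were higher in 14 of 17 members, with a median of 0.35. Adjusted over the list alone, 3 rose, the keratins Krt5, Krt16 and Krt17, and 1 fell, the cornified envelope gene Sprr2a1. None of them passed over all genes tested. Krt5 (chromosome 15, 101707070 to 101712898) was at 222.5 ± 33.2 in wild type and 697.5 ± 47.4 in V118M (SD, n = 2 each; log2 fold change 1.65, standard error 0.18, limma adjusted p = 0.332). Sprr2a1 was at 61 and 46 against 14 and 15. The camera adjusted p was 1.74e-05, and adjusted p = 0.399 with an estimated correlation. The list was not called without V118M replicate 1 (adjusted p = 0.0576). Adjusted over the list alone, 1 member passed without wild-type replicate 1 and 0 without any of the other 3 libraries.

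Germline genes had a median of 0.36 over 15 members, 11 of them higher. Adjusted over the list alone 2 rose, the synaptonemal complex gene Sycp3, listed at 0 in both wild-type libraries and at 26 and 69 in V118M, and Asz1, at 32 and 55 against 129 and 156. None passed over all genes. The camera adjusted p was 0.0133, and adjusted p = 0.399 with an estimated correlation. Without wild-type replicate 2 the median was 0.02, without V118M replicate 2 it was 0.21, and the camera call was lost without either of these or V118M replicate 1. Without V118M replicate 2, where Sycp3 failed the filter on low values, 0 members passed adjusted over the list alone. Without V118M replicate 1, where Sycp3 also failed the filter, Asz1 did not pass and the list median was 0.52. Without wild-type replicate 1 only Sycp3 passed. Sycp3 was among 15 genes listed at 0 in both libraries of a group and at 10 or more in both of the other, where the other pairings of the 4 libraries gave 28 and 31 such genes. Of the 2-cell-like list 4 members could be tested, which is too few for a list test. Of these, Zscan4f, a gene of a family of near-identical copies, stood at 1 and 0 against 16 and 15 and rose adjusted over the list alone, a call kept without wild-type replicate 1 and lost without any of the other 3 libraries.

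Inflammation genes had a median of 0.28 over 23 members, 17 of them higher, and 3 rose adjusted over the list alone: the acute-phase gene Saa3, Lcn2 and the metalloproteinase Mmp3. None passed over all genes. Saa3 was at 24 and 36 against 104 and 168. Without wild-type replicate 1 the list median was 0.15. The camera adjusted p was 0.0114, and adjusted p = 0.399 with an estimated correlation. The list median was 0.42 above the wild-type mean in V118M replicate 2 and 0.08 above it in V118M replicate 1, and without replicate 2 the list was not called (adjusted p = 0.458) and 0 members passed adjusted over the list alone. The call was also lost without V118M replicate 1 (adjusted p = 0.0970), and 0 members passed without it or without wild-type replicate 1. Respiratory chain genes showed a similar split between libraries. Their median over 31 members was 0.28, with 0.58 in V118M replicate 2 and -0.04 in V118M replicate 1 (camera adjusted p = 5.00e-04, and adjusted p = 0.552 with an estimated correlation). Without V118M replicate 2 the adjusted p was 0.458, and without wild-type replicate 1 it was 0.0760 with a median of 0.18. With the length and GC trend removed the median was 0.18, with 25 members higher and 6 lower (adjusted p = 0.00287). The deviation of V118M replicate 2 from the other libraries correlated with transcript length (Spearman's rho -0.458 across genes). For wild-type replicate 1 and V118M replicate 1, whose references include V118M replicate 2, rho was 0.390 and 0.381. The ATP synthase subunit Atp5b was at 19012 and 22718 against 29460 and 29460, and 0 members passed over all genes or adjusted over the list alone. Glycolysis genes had a median of -0.06 over 24 members (camera adjusted p = 0.368), and the glucose transporter Slc2a3 was at 298 and 320 against 208 and 235. The glycolysis median was 0.02 without wild-type replicate 2, 0.03 without V118M replicate 1 and -0.10 without wild-type replicate 1.

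Macrophage and leukocyte genes differed more between replicates than between groups. The list was lower in 14 of 17 members with a median of -0.50 (camera adjusted p = 0.0399, and adjusted p = 0.551 with an estimated correlation), and none passed over all genes or adjusted over the list alone. It was called in 5 of 13 alternatives. The call was lost with a pseudocount of 0.1 (camera adjusted p = 0.0551) and with the replicate block (camera adjusted p = 0.0734). Its median relative to the wild-type mean was 0.68 and -0.68 in wild-type replicates 1 and 2, and -0.97 and -0.11 in V118M replicates 1 and 2. Ptprc, the pan-leukocyte gene for CD45, was at 165 and 58 in wild type and 30 and 0 in V118M. Leaving out wild-type replicate 1 or V118M replicate 1 or 2 gave adjusted p of 0.587, 0.813 and 0.15, with medians of -0.10, -0.11 and -0.95, and leaving out wild-type replicate 2 gave a median of -1.40. Adipocyte and chondrocyte genes were higher in 8 of 9 members by a median of 0.32 (camera adjusted p = 0.0175, and adjusted p = 0.399 with an estimated correlation). This call was lost without wild-type replicate 2 (adjusted p = 0.0516) or either V118M library. The cartilage matrix gene Comp was at 6 and 3 against 12 and 16.

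Other lists were not called. The neural list had a median of 0.20 over 14 members (camera adjusted p = 0.217), and the glial filament gene Gfap rose adjusted over the list alone, from 30 and 30 to 132 and 78, but not when either wild-type library was left out. Endoderm genes, a lineage in which SOX17 acts, had a median of -0.11 over 25 members, and endothelial genes a median of -0.18 over 24 members (camera adjusted p = 0.360 for both). The endothelial median was -0.06 without either V118M library, and the endoderm median was -0.35 without V118M replicate 1, -0.25 without wild-type replicate 2 and -0.02 without V118M replicate 2. In these lists Pth1r was at 133 and 112 against 222 and 247, and Fli1 at 13 and 12 against 28 and 32. The trophoblast median was -0.12 over 11 members, with Gata2 at 607 and 580 against 432 and 381. It was -0.23 without V118M replicate 1, -0.03 without V118M replicate 2, -0.07 without wild-type replicate 1 and 0.05 without wild-type replicate 2. Mesoderm and muscle genes had a median of 0.19 over 15 members, with Myh3 at 2 and 6 against 1 and 0. The mesoderm median was 0.02 without V118M replicate 2 and 0.09 without wild-type replicate 2. Erythroid genes had a median of 0.24 over 7 members, with Hbb-bs at 70 and 54 against 72 and 96. The erythroid median was -0.18 without wild-type replicate 1, 0.06 without V118M replicate 2 and 0.37 without V118M replicate 1. Wnt, Hedgehog and BMP targets had a median of -0.18 over 23 members (camera adjusted p = 0.0670). The Wnt feedback gene Axin2 was at 462 and 474 against 326 and 251, and without wild-type replicate 2 the list was called (adjusted p = 0.0485), as it was with the stricter filter (adjusted p = 0.0153). The Wnt list median was -0.06 without wild-type replicate 1 (adjusted p = 0.239) and -0.07 without V118M replicate 2 (adjusted p = 0.259). Without wild-type replicate 2 the neural list had a median of 0.34 and was called too (adjusted p = 0.0485). The neural list was also called with the stricter filter (median 0.15, adjusted p = 0.0415), and its median was 0.13 without V118M replicate 2. In the sex-linked list, with a median of -0.14 over 6 members, Xist was at 13680 and 12822 against 14864 and 5991. Without V118M replicate 2 the list median was -0.04. Immediate early genes had a median of 0.01 and a mean of -0.10 over 22 members, and camera's direction for the list was lower (adjusted p = 0.360). Their median was -0.04 without wild-type replicate 1 and -0.12 without V118M replicate 2. Fosb in that list was at 90 and 93 against 42 and 28. For the trophoblast, mesoderm, sex-linked and erythroid lists the camera adjusted p was 0.360, 0.360, 0.360 and 0.368. Apart from Gfap, 0 members of these lists passed adjusted over the list alone. The mitochondrially encoded list had 0 members in the table analysed here.

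**Figure D3:**
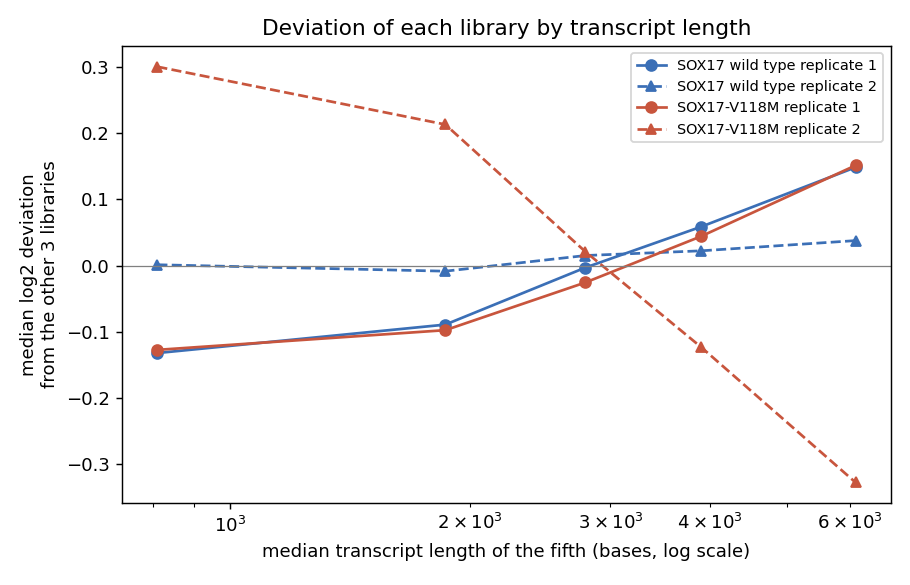
Median deviation (log2) of each library from the mean of the other 3 libraries, for genes divided into 5 equal bins by transcript length, plotted at the median length of each bin on a log axis. V118M replicate 2 runs from 0.30 in the bin of shortest transcripts to -0.33 in the bin of longest.

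The deviation of V118M replicate 2 from the other libraries followed transcript length. Across 12635 genes, which are not independent replicates, Spearman's rho between this deviation and transcript length was -0.458, against 0.390, 0.0777 and 0.381 for wild-type replicates 1 and 2 and V118M replicate 1. The references for these other libraries include V118M replicate 2, whose own trend raises their rho, so they are not separate measures. Over 5 equal bins of genes by length, the median deviation was 0.30 log2 units in the bin of shortest transcripts (median 809.5 bases) and -0.33 in the bin of longest (median 6095 bases).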

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

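The removal of a length and GC trend, array quality weights and counts within lists were chosen after the data had been seen, and the other settings before. The number of genes passing limma's adjusted p of 0.05 was 0 under every setting but the replicate block, which gave 3 genes, all 3 changed by at least 2-fold: Oas2, Ifi27l2a and C4b (adjusted p = 0.0276 each). With 2 pairs, replicate numbers are not shown to pair samples: deviations of same-numbered libraries correlated at 0.0160 across all tested genes and at 0.303 across genes with a mean log2 value of at least 5. The block called 9 lists, against 10 in the fit without it. Adjusted over the list alone it gave 10 risen G2 and M phase genes, against 0, and 7 risen and 2 fallen keratinocyte genes, against 3 and 1. It also added Ptprc as fallen in the leukocyte list and Fabp7, named after its values were seen, as risen in the neural list. The number of lists called was 9 with a pseudocount of 0.1 and 10 with 5, 10 without a filter, 12 with the stricter filter, 11 with the length and GC trend removed and 9 with array weights. It was 0 with an estimated correlation and 0 with fry, which does not compare a list with other genes. Array weights were equal within each group (2.33 and 0.429), so they did not tell replicates apart. Leaving out each library gave 4 to 11 called lists, 4 without V118M replicate 1 and 6 without V118M replicate 2. In these fits a lone library is assumed to vary like the other group, which alone gives the spread. Genes nearly tied within that group can then pass, so members passing in these fits are not read as gains. Of 20 lists with no member passing adjusted over the list alone, 13 had passing members without V118M replicate 1 and 6 without V118M replicate 2. The interferon list was called in 11 of 13 alternatives, at medians of 1.07 to 1.52, and was lost with an estimated correlation and with fry. The pluripotency median stayed positive, and without single libraries ran from 0.0864 to 0.249, passing the threshold without wild-type replicate 2 (0.128). With single libraries left out, the direction turned for the fibroblast (0 to 0.0621), glycolysis (-0.0960 to 0.0300), endoderm (-0.349 to -0.0208), trophoblast (-0.226 to 0.0455) and respiratory chain (-0.0405 to 0.578) lists, and for Xist (-1.14 to 0.17). Direction is camera's, so it can turn while the median keeps its sign. The cause of these turns was not tested. Of the other list results, 37 fell short of the threshold they had passed, 7 newly passed it (pluripotency included) and 262 kept camera's direction and their side. Among these 262 the median changed sign in 6: erythroid and immediate early without wild-type replicate 1, trophoblast and glycolysis without wild-type replicate 2, and immediate early without V118M replicate 2 and with the trend removed. For named genes, 301 repeats kept sign and side, and 11 belonged to Pou5f1, which had no difference to keep. Sox2 without V118M replicate 1 and Klf4 without V118M replicate 2 had a log2 fold change of 0, and Xist turned. Sycp3 gave no value without either V118M library, because it then failed the filter. RLE, upper-quartile and library-size normalization, DESeq2 and limma-voom were not run because they need counts. Depth is unknown, so what it limits cannot be stated.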

Other observations

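The gene lists of this paragraph and the next were written after the values had been seen. So were the tests of a stronger response in V118M replicate 2, of the interferon list without that library, of leukocyte markers and of genes listed at 0. The members of these lists were chosen with values known, so the lists' counts and p-values are descriptive and give no separate support. Of 40 tested interferon-induced genes outside the fixed list, 38 were higher in V118M. Their median log2 fold change was 0.93, and 18 rose adjusted over the list alone. The camera adjusted p over the 5 lists was 4.21e-24, and adjusted p = 0.0677 with an estimated correlation. Ifi27l2a was at 10 and 10 in the wild-type libraries and at 164 and 256 in the V118M libraries. Irf9, the DNA-binding part of the ISGF3 complex that transmits type I interferon signals, was at 220 and 244 against 542 and 468. Genes of MHC class I presentation, 4 of which are also in the list of further interferon genes, were higher in 14 of 16 members by a median of 0.20 (camera adjusted p = 8.59e-04, and adjusted p = 0.305 with an estimated correlation), and 0 passed adjusted over the list alone.

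Complement genes went both ways. Of 13 tested members 8 were higher and 5 lower in V118M, and adjusted over the list alone 2 rose and 1 fell. C4b, which had the smallest p of all genes, was at 184 and 204 in wild type and 1161 and 992 in V118M, and Cfb at 32 and 36 against 172 and 214. The list median was 0.20 (camera adjusted p = 0.00677, and adjusted p = 0.178 with an estimated correlation). Imprinted genes were higher in 15 of 23 members by a median of 0.17 (camera adjusted p = 0.0138, and adjusted p = 0.178 with an estimated correlation), and 1 rose adjusted over the list alone, Mest, at 218 and 200 against 418 and 462. Replication-dependent histone genes had a median of 0 over 22 members (camera adjusted p = 0.174), and of 0.31 without V118M replicate 2.

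The higher interferon list in V118M was set against technical explanations. V118M replicate 2 alone does not account for it, since the list median was 1.07 without that library. A length and GC trend does not account for it either, since the median was 1.22 with the trend removed. More leukocytes in the V118M cultures would raise leukocyte markers there, but their list median was -0.50, and these markers were highest in wild-type replicate 1, where the interferon median was 0.01. The real grouping gave a median of 1.30 and the highest of the other splits 0.130, but 3 splits are too few for a share under 0.05. Differences in virus batch or culture between the groups and an effect of the SOX17 form itself are open and untested, and the design cannot be used to tell them apart.

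V118M replicate 2 lay apart from the other 3 libraries, with a mean squared deviation of 0.265, against 0.0929 for the next. A transcript length trend, as RNA breakdown or library preparation might give, is consistent with its rho of -0.458 between deviation and transcript length. It is not the whole of the difference, because with the length and GC trend removed the mean squared deviation was still 2.59 times that of the next library (2.85 times before). Whether part of it is a stronger form of the response in V118M replicate 1 cannot be told apart from other sources. Differences from wild type in the V118M libraries were correlated across genes, with no library shared and the trend removed. The correlation was 0.0687 with wild-type partners of the other replicate number and 0.261 with partners of the same number. Any likeness of same-numbered libraries would lower the 0.0687, while for the 0.261 it cancels within each difference. The SOX17 form as a source of the rest was not tested further.

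Some genes were listed at 0 in both libraries of a group and at 10 or more in both of the other. There were 15 such genes between wild type and V118M, among them Sycp3 and Nlrp4f (0 and 0 against 28 and 28) on the V118M side and Olfm3 (58 and 50 against 0 and 0) on the wild-type side. The other pairings of the same libraries gave 28 and 31 such genes, so chance dropout may account for the 15. An effect of the SOX17 form on single genes among them is open.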
